A study of Mus musculus with 34 samples.

How the data were processed

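E14 mouse embryonic stem cells were grown with serum and LIF, per the labels' protocols, and carried either a scrambled hairpin (scr) or a hairpin against Zc3h13, which encodes a zinc-finger protein of the m6A methyltransferase complex. RNA-seq libraries of poly(A) RNA came from scr cells, knockdown cells and knockdown cells with Zc3h13 restored (rescue). MeRIP-seq, in which RNA fragments are pulled down with an antibody against N6-methyladenosine (m6A), was done on whole-cell RNA and on cytoplasmic and nuclear RNA, and the fraction inputs were sequenced beside it. A RIP-seq experiment listed RNAs bound by Zc3h13. The labels describe 34 samples, of which 8 (a repeat of the whole-cell m6A samples, the whole-cell inputs and the control and input samples of the RIP) were not used here because they came with no processed values.

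The deposited RNA-seq and input tables give, per RefSeq transcript and per the file headers, the fragment count, this count scaled to the library total (CPM) and FPKM. The counts were deposited as whole numbers without normalization, and CPM values divide by a total that was constant within each library and that exceeded the sum over genes. In the values the authors deposited, FPKM equals CPM divided by the mRNA size in kilobases. The submitters' processing notes name CASAVA 1.4, TopHat2, Cufflinks, Cuffdiff and bedtools and the builds mm9 and NCBIM37, without a role or an order. Whether the counting used strand is not given in the sources used here. Genes that overlap another gene on the opposite strand, or that lie in an intron of a host gene, are therefore uncertain, as are members of near-identical families.

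Peak lists were deposited on mm9. The cytoplasmic and nuclear lists give the exonic blocks of each peak and a column that, per the file headers, is its score, whose values from 0 to 0.01 read as a p-value. The whole-cell lists carry no header, give spans that include introns, and hold a p-value that the authors rounded to 4 decimals, so that 10454 of 12368 scr peaks and 9432 of 11850 knockdown peaks are listed at 0. The peak caller, whether its settings were the same for every list, whether these p-values are adjusted, and whether the whole-cell lists pool replicates are not given in the sources used here. The whole-cell control list is titled as wild type, while its genotype label says scr. Peak p-values are the authors' and served only to rank peaks within a list. The RIP list holds 3389 gene symbols without a measurement.

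Groups were taken from the labels. RNA-seq had 2 scr, 4 knockdown and 1 rescue libraries in 2 deposit sets. Set A held scr 1, knockdown 1, knockdown 2 and the rescue, and set B held scr 2, knockdown 3 (hairpin 1) and knockdown 4 (hairpin 2). The labels do not say which hairpins set A used, nor which the knockdown fraction inputs and m6A lists used. Each fraction had 2 scr and 2 knockdown inputs and as many m6A lists. Nothing in the labels says that replicates came from separate cultures, so p-values of comparisons between libraries measure only the spread between these samples, which may be technical. Fisher and permutation p-values of gene groups measure spread across genes, which are not replicates, and leave out the spread between libraries. A chi-square comparison of counts found no pair of libraries that agreed within sampling noise.

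The tables held 35830 transcripts of 24404 gene symbols. For the 6056 symbols with several transcripts, the longest annotated mRNA stood for the gene, because transcripts of a gene share fragments, and 375 symbols had an accession at several loci. Of 11194 Ensembl gene identifiers in the peak lists, 10410 matched a symbol. A RefSeq table on GRCm38 was used for names only. Ribosomal RNA (Rn45s) took 13.9% to 33.8% of fraction fragments and Lars2, which can take up mitochondrial ribosomal RNA, 1.77% to 4.53%, against at most 0.11% and 0.03% in RNA-seq.

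The planned test had been limma on log2(FPKM + 1). Because whole-number counts were found, the main test was edgeR's quasi-likelihood test on counts with TMM factors for genes with a mean FPKM of at least 1, and the planned test became an alternative. RNA-seq fits had a set term (11605 genes), and the 8 fraction inputs were fitted together (10847 genes). Adjusted p-values are two-sided Benjamini-Hochberg values, with 0.05 as the threshold. Fold changes are log2 values ± SE and levels are TMM-scaled CPM ± SD, unless stated otherwise. Agreement of the sets, the rescue and the comparisons of gene groups used log2(FPKM + 1), which understates changes of low genes.

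Same-numbered fraction libraries deviated together from their group means in all 6 pairs of groups, with Pearson correlations of 0.569 to 0.734 across genes against a threshold of 0.1. The numbers were therefore read as pairing the fraction libraries. This reading comes from the data, since the labels do not say what a number stands for, and the fit with the number as a block is given beside results it changes. Number 1 inputs held 26.8 to 37.5 M total fragments and number 2 inputs 18.6 to 20.7 M. Shared cultures and a shared preparation or sequencing run therefore cannot be told apart.

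Peaks shared a site when they overlapped by at least 1 bp on the same strand, and sites were merged across the 4 lists of a fraction. Overlaps of whole-cell peaks also had to lie in the same gene. A lost site had a peak in both scr lists and in neither knockdown list, and a gained site the opposite. A peak was near a start within 500 bp of an annotated transcript start and near an end within 1000 bp of an annotated end. Peak numbers were compared with exact two-sided permutation tests, of which 6 splits exist per fraction. Whole-cell peaks, which have 1 list per condition, were compared by overlap with 95% Wilson intervals, which cover counting error only. Expressed genes were classed as lost (a whole-cell scr peak, none overlapping a knockdown peak), kept (an overlapping pair) or without any whole-cell peak. Medians of these groups were compared by 100000 two-sided permutations within 5 bins of expression, and 6 such comparisons were adjusted together. RIP overlaps used Fisher's exact test and permutations within the same bins over the 11605 expressed genes.

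A total of 22 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. They cover m6A writers, m6A readers and erasers, naive pluripotency, primed pluripotency, neural ectoderm, mesoderm, endoderm, trophectoderm, the 2-cell-like state, imprinted genes, fibroblasts, p53 targets, interferon, ATF4 and unfolded protein response, immediate early genes, cell cycle, hypoxia and glycolysis, nuclear RNAs, mitochondrially encoded RNAs, ribosomal proteins, replication-dependent histones and KRAB zinc fingers. No mitochondrially encoded gene was among the genes tested. The rule for named genes, fixed at the same time, took Zc3h13, the writers, Pou5f1, Nanog, Sox2, Klf4, Esrrb and Zfp42, the 10 genes with the largest changes in each direction among those past the threshold and changed the same way in every set or numbered pair, and the members of each list with the smallest p. Predicted and clone-named genes were counted but not named. Results of some genes that the rule takes are not reported here. Peaks were described for the same pluripotency genes, Zc3h13, Myc, Jun, Junb and Tet1 and for the genes with the most lost sites.

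The tests were tried on simulated counts with 200 changed genes. At 1.5-fold, 2-fold and 4-fold, the RNA-seq fit recovered 56.7%, 89.6% and 98.5% of the changed genes. Fraction counts were simulated from the model with the block, so higher shares with the block were fixed in advance. They do not speak for the block in the real data. The cytoplasmic fit recovered 1.5%, 35.8% and 92.4%, and 74.6%, 91% and 97% with the block. The nuclear fit recovered 4.5%, 43.3% and 97%, and 79.1%, 92.5% and 98.5% with the block. For the difference between fractions the shares were 0%, 1.5% and 74.2%, and 41.8%, 80.6% and 98.5% with the block, and for nucleus against cytoplasm 7.5%, 49.3% and 93.9%, and 71.6%, 92.5% and 97%. A list of 25 genes raised 1.5-fold gave a camera p of 4.9e-46, and 2 of 100 random lists fell below 0.05. Genes were simulated independently of each other, so this check could not show false calls of lists whose members vary together.

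Alternatives were limma on log2(FPKM + 1) and log2(FPKM + 0.1), quantile and median scaling, DESeq2, relative log expression factors, no filter or a mean FPKM of at least 5, fits without the set term or within a set, and each library left out in turn. Peak alternatives were an overlap of at least 50% of the shorter peak, peaks below each list's median p, expressed genes, and lists shortened to equal length. DESeq2, relative log expression, fits without Rn45s and Lars2, estimated correlations with the block, single-block peaks, edgeR fold changes in the comparisons of gene groups, bins that include mRNA length, and lost peaks of bound genes among genes with a scr peak were chosen after seeing the data. Computation used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.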

Results

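The series compared E14 mouse embryonic stem cells carrying a scrambled hairpin (scr) with cells depleted of Zc3h13, to map which RNAs and which m6A marks depended on this zinc-finger protein. Data came from RNA-seq of 2 scr, 4 knockdown and 1 rescue libraries, from inputs of the cytoplasmic and nuclear fractions (2 scr and 2 knockdown libraries each), from m6A peak lists of whole cells (1 per condition) and of each fraction (2 per condition), and from a list of Zc3h13-bound RNAs. RNA-seq libraries held 28.7 to 48.8 M fragments in genes and fraction inputs 9.5 to 30 M.

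Zc3h13 RNA was lower in every knockdown library than in every scr library of the same kind. Fragment counts scaled to library size (CPM) were 124 and 132 in scr, and 19.3, 16.3, 25.5 and 19.3 in knockdown 1 to 4. The rescue library stood at 345. The fitted log2 change was -2.75 ± 0.12 (SE, 2 scr and 4 knockdown libraries; edgeR quasi-likelihood adjusted p = 0.000363), with -2.82 in set A and -2.63 in set B. In the cytoplasm, CPM values were 54.2 and 41.5 in scr and 8.01 and 8.33 in knockdown. In the nucleus they were 324 and 337 in scr and 61.1 and 56.9 in knockdown.

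**Figure D1:**
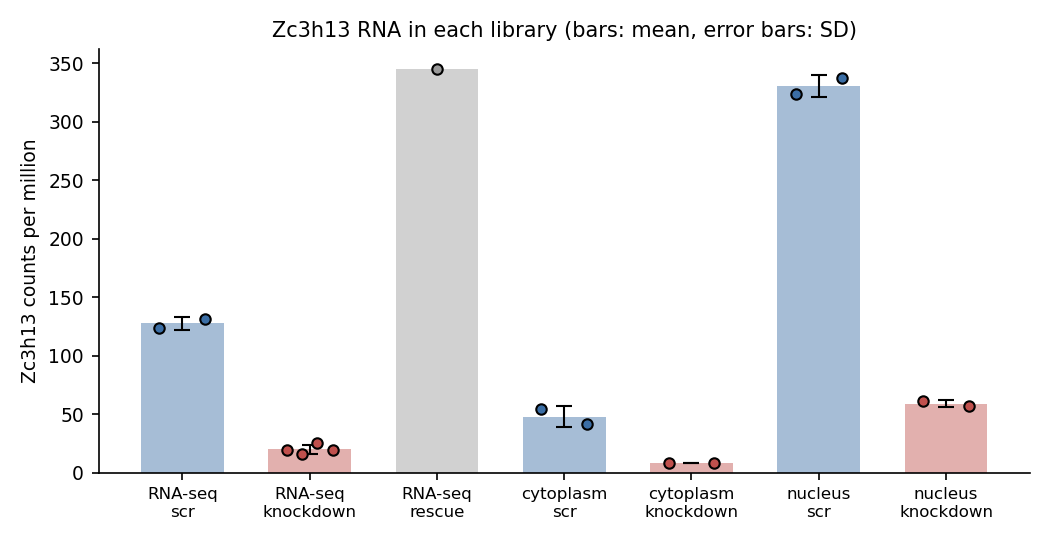
Zc3h13 CPM (linear axis) in RNA-seq and in the fraction inputs, with a point per library, bars for the group mean and error bars for the SD. The 4 RNA-seq knockdown libraries lie between 16.3 and 25.5, below both scr libraries (124 and 132), and the single rescue library is at 345.

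Comparing whole-cell RNA of knockdown and scr cells, which asks what RNA levels follow the loss of Zc3h13, found changes in both directions, such as lower Klf4 and higher Col4a1. Klf4 fell from 185 ± 25.8 CPM (SD, n = 2) to 93.2 ± 31.5 (n = 4), and Nanog from 485 ± 150 to 297 ± 105. Col4a1, a basement-membrane collagen chain, rose from 18 ± 1.39 to 115 ± 11.9. The fetal growth factor gene Igf2 rose from 3.18 ± 0.118 to 29.7 ± 10.3. Neat1, the long noncoding RNA of paraspeckles, fell from 280 ± 44.1 to 63.0 ± 17.7, and Asns, which encodes asparagine synthetase, from 396 ± 114 to 162 ± 27.2. Of 11605 genes tested, 5437 passed an adjusted p of 0.05 (edgeR quasi-likelihood test), 2749 higher and 2688 lower. The planned limma test on log2(FPKM + 1) called 3600 higher and 1807 lower, with a median over all genes of 0.089, and on log2(FPKM + 0.1) 3630 and 1788, with a median of 0.10. Without scr 1 the count was 2801 and without scr 2 it was 3217. The edgeR adjusted p of Klf4 and Nanog was then 0.157 and 0.18 (without scr 1), and 0.0877 and 0.145 (without scr 2).

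Among the largest rises of genes moving the same way in both sets were those in Hs6st2 (3.79 ± 0.46), a heparan sulfate sulfotransferase, and Arsb (3.67 ± 0.18), a lysosomal sulfatase. Others were in the ubiquitin ligase gene Rnf217 (3.35 ± 0.29), the immunity-related GTPase gene Irgm1 (3.33 ± 0.30), Igf2 (3.18 ± 0.28) and Anxa3 (3.07 ± 0.28). The largest falls besides Zc3h13 were in Pla2g1b (-3.62 ± 0.36), a secreted phospholipase, Dnah8 (-3.22 ± 0.10), an axonemal dynein chain, and the growth factor gene Fgf1 (-3.14 ± 0.17). Lrrc31 (-2.96 ± 0.40), the histone gene Hist3h2a (-2.85 ± 0.36), the galectin gene Lgals3 (-2.67 ± 0.21) and Lncenc1 (-2.58 ± 0.25), a long noncoding RNA of naive stem cells, also fell.

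Among 33 naive pluripotency genes, 0 rose and 23 fell (edgeR; adjusted over the list alone, 1 and 24). Camera placed the list below other genes (adjusted p = 1.31e-06, adjusted p = 0.321 with an estimated correlation). Klf4 (-1.01 ± 0.24), Klf5 (-1 ± 0.14), Esrrb (-0.88 ± 0.18), Nanog (-0.72 ± 0.19), Sox2 (-0.63 ± 0.06), Zfp42 (-0.62 ± 0.16) and Pou5f1 (-0.47 ± 0.06), which encode transcription factors of the pluripotent state, fell. As for Klf4 and Nanog, left-out libraries ended the edgeR calls of Esrrb and Zfp42, at adjusted p-values of 0.111 and 0.191 without scr 1, and 0.0758 and 0.0943 without scr 2.

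Among 17 primed pluripotency genes, 4 rose and 4 fell (list alone, 4 and 4; camera adjusted p = 0.69), with Fzd2, a Wnt receptor, at 2.21 ± 0.18 and Etv5 at -0.38 ± 0.06. Of 11 endoderm genes, 8 rose and 2 fell, the same numbers as adjusted over the list alone (camera, higher, adjusted p = 7.07e-07, adjusted p = 0.229 with an estimated correlation). Col4a1 (2.66 ± 0.12), Col4a2 (2.85 ± 0.18), the endocytic adaptor gene Dab2 (2.70 ± 0.16) and the keratin gene Krt19 (1.42 ± 0.17) rose. Of 7 mesoderm genes, 3 rose and 1 fell (list alone, 4 and 1; camera adjusted p = 0.0838), among them Snai1 (2.38 ± 0.15), a repressor of epithelial genes. Of 9 neural ectoderm genes, 2 rose and 3 fell (list alone, 3 and 3; camera adjusted p = 0.69), with the intermediate filament gene Nes at 1.20 ± 0.15 and the tubulin gene Tubb3 at -0.89 ± 0.06. The neural list's median was 0.23 while camera pointed down. Of 4 trophectoderm genes, 1 rose and 1 fell (list alone, 1 and 1; camera adjusted p = 0.958, pointing down with a median of 0.46), namely Ascl2 (1.06 ± 0.24) and Tfap2c (-1.77 ± 0.24). Without scr 1 the adjusted p of Ascl2 was 0.103, and without knockdown 2 the mesoderm list had an adjusted p of 0.0453.

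Of 6 genes of the 2-cell-like state, 1 rose and 0 fell (edgeR; list alone, 1 and 0; camera adjusted p = 0.325), Eif1a at 0.49 ± 0.06, while Zscan4c had a change of 1.38 ± 1.02 (adjusted p = 0.306). Of 6 fibroblast genes, 4 rose and 1 fell (list alone, 4 and 1; camera, higher, adjusted p = 0.0361, adjusted p = 0.433 with an estimated correlation), among them Fbn1 (1.65 ± 0.12), a microfibril component, and Twist1 (2.51 ± 0.33). Without scr 1, scr 2 and knockdown 4 the fibroblast list had adjusted p-values of 0.0700, 0.133 and 0.0595, and with limma on log2(FPKM + 0.1) 0.279.

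Among 11 m6A writer genes, 3 rose and 4 fell (list alone, 3 and 4; camera adjusted p = 0.377). Rbm15 (0.75 ± 0.08), an RNA-binding adaptor, Virma (listed as 1110037F02Rik; 0.61 ± 0.06), the complex's scaffold, and Cbll1 (0.51 ± 0.11) rose. Besides Zc3h13, the catalytic subunit gene Mettl3 (-0.60 ± 0.08), its partner Mettl14 (-0.31 ± 0.08) and the ribosomal RNA methyltransferase gene Mettl5 (-0.30 ± 0.09) fell. Wtap (-0.06 ± 0.07), Mettl16 (-0.10 ± 0.10), Rbm15b (0.17 ± 0.09) and Zcchc4 (-0.09 ± 0.10) did not pass. The edgeR call of Mettl14 ended without scr 1 (adjusted p = 0.144) and scr 2 (0.0743), and that of Cbll1 without scr 2 (0.111). That of Mettl5 ended without scr 1 (0.287), knockdown 1 (0.0776), knockdown 2 (0.0797) and knockdown 4 (0.0914). Of 13 m6A readers and erasers, 6 rose and 1 fell (list alone, 6 and 2; camera adjusted p = 0.0554), with Ythdf2 (1.02 ± 0.06), which promotes decay of m6A-marked RNA, and the nuclear reader gene Ythdc1 (1.14 ± 0.10) higher. This list passed without scr 1 (0.0294), knockdown 1 (0.048) and knockdown 3 (0.0469).

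Of 21 ATF4 and unfolded protein response genes, 1 rose and 15 fell, the same numbers as adjusted over the list alone (camera, lower, adjusted p = 1.91e-08, adjusted p = 0.321 with an estimated correlation). Asns (-1.28 ± 0.06), the seryl-tRNA synthetase gene Sars (-1.11 ± 0.11), Shmt2 (-0.74 ± 0.05) of serine metabolism and Aars (-0.56 ± 0.05) fell. Of 25 cell cycle genes, 2 rose and 16 fell, as adjusted over the list alone (camera, lower, adjusted p = 1.18e-04, adjusted p = 0.433 with an estimated correlation). The spindle motor gene Kif11 (-0.70 ± 0.05), Cdc20 (-0.67 ± 0.05), which activates the anaphase-promoting complex, and the spindle checkpoint gene Bub1b (-0.60 ± 0.05) fell. Of 46 ribosomal protein genes, 0 rose and 25 fell (edgeR; list alone, 1 and 25; camera, lower, adjusted p = 8.12e-04, adjusted p = 0.559 with an estimated correlation), among them Rpl24 (-0.40 ± 0.05) and Rps6 (-0.39 ± 0.05). The ribosomal list's median hung on the scaling, at -0.19 in edgeR, -0.08 with limma on log2(FPKM + 1) and -0.01 on quantile-scaled values. Of 10 nuclear RNAs, 0 rose and 7 fell, as adjusted over the list alone (edgeR; camera, lower, adjusted p = 8.12e-04, adjusted p = 0.321 with an estimated correlation), with Neat1 at -2.15 ± 0.25 and the X-linked Firre at -0.99 ± 0.06. Of 15 immediate early genes, 4 rose and 1 fell, as adjusted over the list alone (camera, higher, adjusted p = 0.0243, adjusted p = 0.433 with an estimated correlation). Cyr61 (2.33 ± 0.15) and Ctgf (1.86 ± 0.13), which encode secreted matricellular proteins, and Jund (0.91 ± 0.09) rose. The immediate early list had an adjusted p of 0.179 without scr 1 and 0.294 with limma on log2(FPKM + 0.1).

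Of 19 imprinted genes, 8 rose and 4 fell, as adjusted over the list alone (camera adjusted p = 0.377, pointing up with a median of -0.01), with Igf2 and H19 (2.36 ± 0.21) higher and Meg3 (-0.96 ± 0.10) lower. Of 19 p53 targets, 9 rose and 2 fell (list alone, 10 and 2; camera adjusted p = 0.0981), among them Aen (0.69 ± 0.09), a nuclease gene, and Sesn2 (-0.60 ± 0.07). Of 10 interferon and RNA-sensing genes, 1 rose and 5 fell (list alone, 1 and 5; camera adjusted p = 0.0981), including the RNA sensor gene Ddx58 (-1.14 ± 0.15). Of 18 hypoxia and glycolysis genes, 3 rose and 6 fell (list alone, 3 and 6; camera adjusted p = 0.31), with the oxygen sensor gene Egln1 at 1.04 ± 0.17 and Vegfa at -0.79 ± 0.08. Of 4 replication-dependent histone genes, 0 rose and 2 fell (edgeR; list alone, 0 and 2; camera adjusted p = 0.0981), Hist3h2a and Hist1h1c (-1.17 ± 0.27, adjusted p = 0.163 without scr 2). Of 18 KRAB zinc-finger genes, 3 rose and 3 fell (list alone, 0 and 1; camera adjusted p = 0.69, pointing down with a median of 0.00), with Zfp819 at -0.96 ± 0.14. In single left-out fits, lists passed that did not pass in the full fit. These were hypoxia (0.0442) and histones (0.0386) without scr 1, p53 (0.0159) and KRAB (0.0289) without scr 2, interferon without knockdown 1 (0.048) and 3 (0.0462), p53 and histones (both 0.0329) without knockdown 2, and p53 (0.0308) without knockdown 4.

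**Figure D2:**
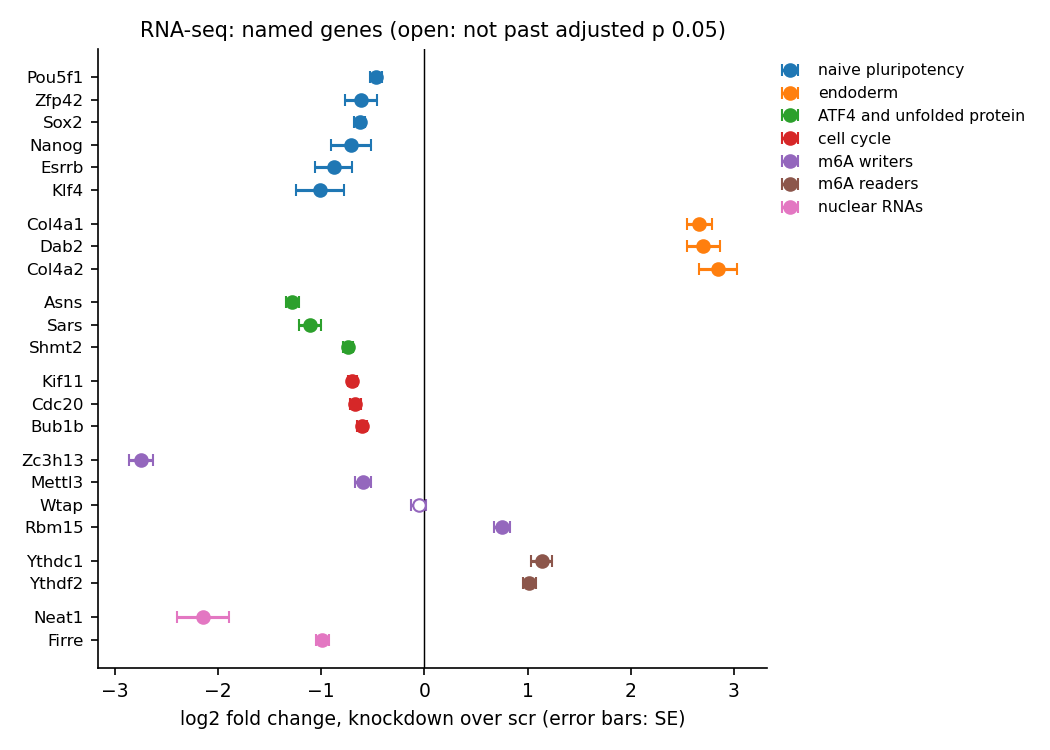
Log2 fold change of some of the named genes in RNA-seq (x axis, knockdown over scr, edgeR, error bars 1 SE), coloured by gene list, with open points for genes that did not pass an adjusted p of 0.05. The naive pluripotency genes shown lie between -1.01 (Klf4) and -0.47 (Pou5f1), Col4a1, Dab2 and Col4a2 between 2.66 and 2.85, and Wtap (-0.06) is the only open point among the genes shown.

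Set A and set B, analysed apart, gave fold changes that correlated across genes (Pearson 0.814, Spearman 0.815, 11605 genes; genes are not replicates), and 82.9% of genes had the same sign. Within sets, 1855 genes passed in set A and 2257 in set B, and 3048 passed without the set term. Klf4 had an adjusted p of 0.0689 in set A and 0.0712 in set B.

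The rescue library, which asks whether restoring Zc3h13 returns RNA levels, had no replicate, so its values carry no test. Genes were chosen in set B as changed at least 1.5-fold with both hairpins, and compared in set A, where the rescue belongs. Of 1364 such genes, 1281 (93.9%, Wilson 92.5% to 95.1% across genes) lay on the scr side of knockdown in the rescue. Among 1000 genes higher in knockdown the median change from knockdown was -0.75 in the rescue and -0.83 in scr, and among 364 lower genes it was 0.73 and 0.86, where both changes share the set A knockdown libraries. FPKM of Nanog was 139.62 in scr, 88.82 in knockdown (mean) and 185.63 in the rescue, and of Klf4 44.77, 21.79 and 56.98. Asns stood at 133.45, 62.62 and 129.87, Neat1 at 12.21, 2.51 and 13.95, and Col4a1 at 2.34, 14.2 and 4.27. Dnah8 (6.09, 0.64 and 3.89) lay between knockdown and scr.

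Comparing input RNA of the cytoplasm in knockdown and scr cells asked which RNAs changed where they are translated. Klf4 and Asns fell, and Col4a1 rose. Ccno (3.83 ± 0.29), Ccr4 (3.66 ± 0.34), Efnb2 (3.56 ± 0.19), Igf2 (3.24 ± 0.27) and the protease gene Adamts1 (3.09 ± 0.29) had some of the largest rises among genes moving the same way in both numbered pairs. Nkx6-3 (-3.98 ± 0.37), Pla2g1b (-3.82 ± 0.30), Tmem81 (-3.63 ± 0.34), Cdc42ep1 (-2.95 ± 0.26) and the stress-induced genes Nupr1 (-2.88 ± 0.27) and Gdf15 (-2.61 ± 0.38) fell. In RNA-seq, Ccno and Efnb2 were lower in knockdown 1 than 2 (log2(CPM + 1) differences of -1.28 and -1.21). They were also lower in knockdown 3 than 4 (-1.32 and -1.53), which carried hairpins 1 and 2. The labels do not name the hairpin of the fraction libraries. Of 10847 genes, 2622 passed (edgeR, 1316 higher and 1306 lower), and 5897 (2914 and 2983) with the replicate number as a block. Without cytoplasmic scr 2 the count was 1744, without knockdown 1 it was 1042 and without knockdown 2 it was 933. Knockdown 1 held 33.8% of its gene fragments in Rn45s, against 13.9% to 19.7% in the other cytoplasmic libraries.

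In the cytoplasm, 1 of 33 naive pluripotency genes rose and 16 fell (list alone, 1 and 17; camera adjusted p = 1.56e-07, adjusted p = 0.0578 with an estimated correlation). Klf4 (-1.59 ± 0.13), Klf5 (-1.23 ± 0.11), Esrrb (-1.01 ± 0.14), Nanog (-0.97 ± 0.11), Zfp42 (-0.62 ± 0.12) and Sox2 (-0.57 ± 0.13) fell. Pou5f1 changed by -0.53 ± 0.19 (edgeR adjusted p = 0.0723; 2.07e-05 with the block; 0.0455 without scr 1). Of 20 ATF4 and unfolded protein response genes, 0 rose and 16 fell (edgeR; list alone, 1 and 18; camera adjusted p = 1.30e-14, adjusted p = 0.206 with an estimated correlation), among them Asns (-2.02 ± 0.14), Psat1 (-1.50 ± 0.12) of serine synthesis and Chac1 (-1.75 ± 0.18). Of 46 ribosomal protein genes, 0 rose and 16 fell, and 44 fell with the block (edgeR; list alone, 0 and 19; camera adjusted p = 2.84e-05, adjusted p = 0.621 with an estimated correlation), Rpl7 at -0.84 ± 0.14. The size of this shift hung on the scaling, with a list median of -0.47 in edgeR and -0.08 on quantile-scaled values. Of 25 cell cycle genes, 1 rose and 8 fell, and 19 fell with the block (list alone, 1 and 13; camera adjusted p = 3.39e-04, adjusted p = 0.206 with an estimated correlation), including Bub1b (-0.87 ± 0.11) and Plk1 (-0.92 ± 0.13). Of 12 nuclear RNAs, 0 rose and 4 fell, and 1 rose and 7 fell with the block (edgeR; list alone, 0 and 4; camera adjusted p = 0.021, adjusted p = 0.621 with an estimated correlation), Neat1 at -2.02 ± 0.20. Of 9 endoderm genes, 6 rose and 1 fell (list alone, 6 and 1; camera adjusted p = 0.00699, adjusted p = 0.519 with an estimated correlation), with Col4a1 at 2.17 ± 0.15, Col4a2 at 2.10 ± 0.19 and the laminin gene Lama1 at -1.49 ± 0.14. Single left-out libraries ended some edgeR calls. Without knockdown 1 the adjusted p was 0.0531 for Zfp42, 0.136 for Sox2 and 0.0527 for Rpl7. Without knockdown 2 it was 0.0833 for Zfp42 and 0.0636 for Sox2, and without scr 2 it was 0.0569 for Sox2.

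Of 13 m6A readers and erasers, 4 rose and 0 fell in the cytoplasm, and 7 rose and 1 fell with the block (edgeR; list alone, 4 and 0; camera adjusted p = 0.0364, adjusted p = 0.632 with an estimated correlation), among them Ythdf2 (1.05 ± 0.15) and the demethylase gene Alkbh5 (0.80 ± 0.15). Among the writers, Rbm15 (1.43 ± 0.26) rose, and Zc3h13 (-2.49 ± 0.15), Mettl3 (-0.84 ± 0.13) and Mettl5 (-0.80 ± 0.21) fell. The camera test did not pass for the other lists (adjusted p from 0.112 to 0.996). Of 18 histone genes, 0 rose and 0 fell, and 4 rose with the block (edgeR). The edgeR adjusted p of Mettl5 was 0.173 without knockdown 2 and 0.121 without scr 1.

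Comparing nuclear RNA of knockdown and scr cells found lower Gdf15 and Tbx3 and higher Igf2 and Krt19, with 2445 genes past the edgeR threshold (1120 higher and 1325 lower), and 5672 (2803 and 2869) with the block. Adamts1 (4.26 ± 0.28), the chemokine receptor gene Ccr4 (4.22 ± 0.25), Anxa3 (3.85 ± 0.23), Igf2 (3.6 ± 0.29), Krt19 (3.09 ± 0.40) and the endothelial transcription factor gene Sox18 (3.06 ± 0.35) had some of the largest rises. Gdf15 (-3.61 ± 0.41), Lrrc31 (-3.49 ± 0.26), Nupr1 (-3.49 ± 0.33), Pla2g1b (-3.34 ± 0.30), Nkx6-3 (-3.18 ± 0.37) and Jdp2 (-3.04 ± 0.29) fell. Without nuclear scr 1 the count was 1116, without scr 2 it was 832, without knockdown 1 it was 1082 and without knockdown 2 it was 1579.

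In the nucleus, 2 of 33 naive pluripotency genes rose and 15 fell, and 4 rose and 22 fell with the block (list alone, 3 and 18; camera adjusted p = 6.97e-06, adjusted p = 0.0935 with an estimated correlation). Klf4 (-1.25 ± 0.13), Tbx3 (-1.42 ± 0.13), Esrrb (-1.04 ± 0.14), Nanog (-0.87 ± 0.11) and Zfp42 (-0.85 ± 0.12) fell. Sox2 (-0.35 ± 0.13, adjusted p = 0.091) and Pou5f1 (-0.35 ± 0.19, adjusted p = 0.208) passed only with the block (7.70e-04 and 0.0011). Of 20 ATF4 and unfolded protein response genes, 0 rose and 15 fell (edgeR; list alone, 1 and 16; camera adjusted p = 3.24e-08, adjusted p = 0.308 with an estimated correlation), including Asns (-1.38 ± 0.13) and Chac1 (-1.68 ± 0.19). Of 9 endoderm genes, 6 rose and 2 fell (list alone, 6 and 2; camera adjusted p = 1.21e-04, adjusted p = 0.308 with an estimated correlation), with the keratin gene Krt8 at 1.82 ± 0.17 and Lama1 at -1.74 ± 0.13. Of 13 m6A readers and erasers, 7 rose and 0 fell, and 11 rose with the block (edgeR; list alone, 7 and 0; camera adjusted p = 0.00107, adjusted p = 0.544 with an estimated correlation), among them Ythdf2 (1.15 ± 0.15) and Alkbh5 (0.91 ± 0.15).

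Of 15 immediate early genes, 5 rose and 1 fell in the nucleus (list alone, 5 and 1; camera adjusted p = 0.00241, adjusted p = 0.361 with an estimated correlation), including Jun (1.84 ± 0.21) and Ctgf (2.39 ± 0.17). Of 16 primed pluripotency genes, 5 rose and 2 fell, and 9 rose and 3 fell with the block (list alone, 6 and 3; camera adjusted p = 0.0181, adjusted p = 0.308 with an estimated correlation), including Fzd2 (2.01 ± 0.27) and Sall2 (1.18 ± 0.16). Of 12 nuclear RNAs, 0 rose and 3 fell, and 1 rose and 8 fell with the block (edgeR; list alone, 0 and 4; camera adjusted p = 0.0103, adjusted p = 0.504 with an estimated correlation), including Firre (-1.56 ± 0.15) and Meg3 (-1.07 ± 0.11). Of 9 interferon genes, 0 rose and 5 fell, and 2 rose and 6 fell with the block, among them Stat2 at -0.96 ± 0.14 (edgeR; list alone, 1 and 5; camera adjusted p = 0.0396, adjusted p = 0.308 with an estimated correlation), a list call that ended with the block (0.11). The camera test did not pass for the other lists (adjusted p from 0.131 to 0.636). Of 46 ribosomal protein genes, 0 rose and 0 fell, and 4 rose and 20 fell with the block (edgeR). The median of this list was -0.14 and turned to 0.18 with limma on log2(FPKM + 1), where the median over all genes was 0.25. Among the writers, Virma (0.87 ± 0.18) and Mettl16 (0.68 ± 0.15) rose and Zc3h13 (-2.65 ± 0.15) and Mettl3 (-0.60 ± 0.14) fell. Without knockdown 1 the edgeR adjusted p was 0.0591 for Virma, 0.0756 for Mettl16 and 0.0897 for Mettl3, and without scr 2 it was 0.0886, 0.103 and 0.105. That of Mettl3 was also 0.0717 without scr 1 and 0.0583 without knockdown 2.

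Scaling moved direction in the fractions. With limma on log2(FPKM + 1) the median over all genes was -0.11 in the cytoplasm, 0.25 in the nucleus, 0.35 for their difference and -0.58 for nucleus over cytoplasm in scr. The calls were then 168 higher and 348 lower in the cytoplasm, 541 and 174 in the nucleus, 19 and 16 for their difference, and 1067 and 4987 for nucleus over cytoplasm. The edgeR changes given here are relative to the TMM reference.

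**Figure D3:**
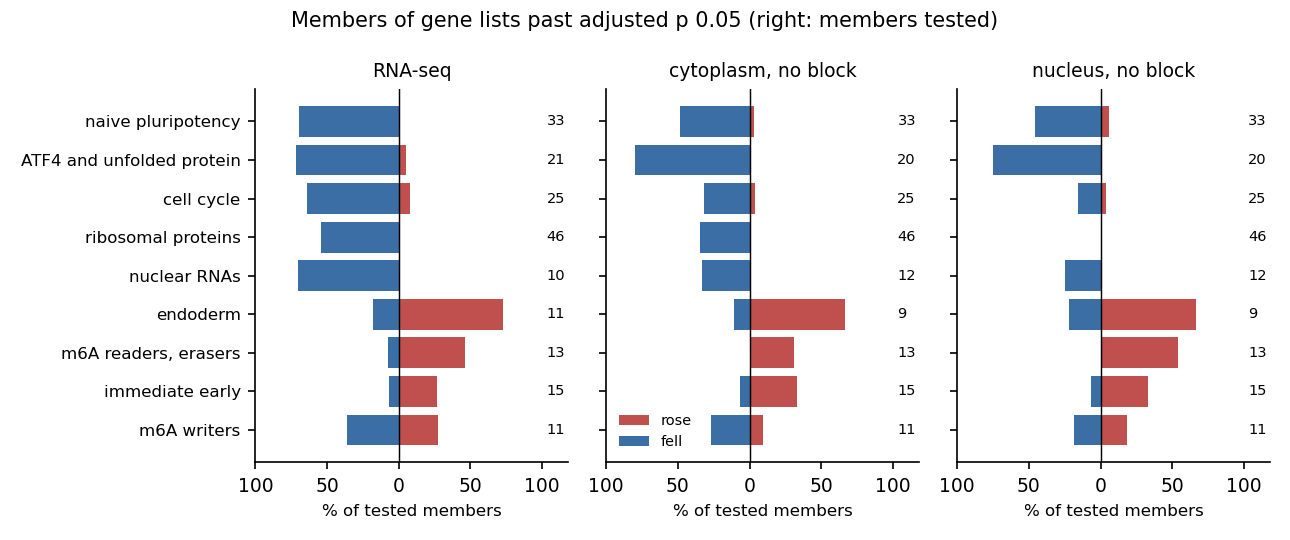
Share of tested list members that rose (red, right) or fell (blue, left) at an edgeR adjusted p of 0.05, in percent, in RNA-seq and in both fractions without the block, with the number tested at the right. Of the naive pluripotency genes 23, 16 and 15 of 33 fell; for ribosomal proteins 25 fell in RNA-seq, 16 in the cytoplasm and 0 in the nucleus, where the list's median turned from -0.14 to 0.18 with limma on log2(FPKM + 1), against a median of 0.25 over all genes.

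Whether the knockdown effect differed between nucleus and cytoplasm was tested as an interaction. No gene passed without the block (0 of 10847 in edgeR, 1494 at an unadjusted p under 0.05, 35 with limma and 108 with DESeq2), and 2524 passed with the block (1278 and 1246). The genes with the smallest p all had an adjusted p of 0.114 without the block. Relative to the cytoplasm, the nuclear change was more positive for Neat1 (1.54 ± 0.26, blocked adjusted p = 1.52e-06), for the aminoacyl-tRNA synthetase gene Eprs (1.22 ± 0.20, 2.52e-06) and for Krt8 (1.31 ± 0.23, 1.28e-05). Neat1 stood at 33.4 ± 2.69 in scr and 8.26 ± 2.31 in knockdown in the cytoplasm, and at 132 ± 8.87 and 94.0 ± 8.17 in the nucleus (CPM, SD, n = 2). The change was more negative for the actin nucleator gene Diaph1 (-1.38 ± 0.16, 1.51e-07), Ndor1 (-1.37 ± 0.17, 3.04e-07), the splicing regulator gene Rbm4b (-2.02 ± 0.27, 1.11e-06) and Zfp57 (-0.97 ± 0.17, 9.48e-06), which maintains imprints. Among the writers, Rbm15 differed with the block (-1.21 ± 0.36, 3.14e-04; 0.23 without), while Zc3h13 did not (-0.16 ± 0.20, 0.446; 0.763 without). Of 46 ribosomal protein genes, 0 passed without the block and 20 were more positive with it (edgeR; camera adjusted p = 6.17e-05, adjusted p = 0.736 with an estimated correlation). Of 25 cell cycle genes, 0 passed without and 11 were more positive with the block (edgeR; camera adjusted p = 0.00154, adjusted p = 0.736 with an estimated correlation). The size of both shifts hung on the scaling, with a median of 0.31 for ribosomal proteins and 0.28 for the cell cycle in edgeR, 0.02 and 0.16 on quantile-scaled values, and 0.75 and 0.71 with limma on log2(FPKM + 1), where the median over all genes was 0.35.

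Comparing nuclear with cytoplasmic RNA in scr cells gave the background against which these changes lie, with 6745 of 10847 genes past the edgeR threshold (3518 higher in the nucleus and 3227 lower; 2644 and 3718 on quantile-scaled values, with a median over all genes of -0.14, and -0.12 on median-centred values). All 12 nuclear RNAs tested were higher in the nucleus (list alone, 12 and 0; camera adjusted p = 4.04e-18, adjusted p = 0.178 with an estimated correlation), among them the imprinting regulator Kcnq1ot1 (6.35 ± 0.46), Xist (5.46 ± 0.31), Meg3 (3.75 ± 0.13) and Firre (3.64 ± 0.16). Zc3h13 mRNA was higher in the nucleus too (2.81 ± 0.15), as were Mki67 (3.55 ± 0.26), a proliferation marker, the DNA demethylase gene Tet1 (2.55 ± 0.30), the spectrin gene Sptbn1 (5.87 ± 0.20) and Omd (6.67 ± 0.65). Values of Omd, Kcnq1ot1 and Xist are uncertain where counts take in RNA of a host gene or of the opposite strand. Of 46 ribosomal protein genes 0 were higher and 36 lower in the nucleus (edgeR; list alone, 0 and 37; camera adjusted p = 4.62e-11, adjusted p = 0.397 with an estimated correlation), such as Rps4x (-1.72 ± 0.14). The splicing factor gene Snrpd1 (-2.15 ± 0.24), Pin4 (-2.08 ± 0.24), S100a11 (-1.99 ± 0.18) and Hprt (-1.82 ± 0.20) were lower as well.

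Among the other lists, 4 cell cycle genes were higher in the nucleus and 17 of 25 lower (list alone, 4 and 17; camera adjusted p = 0.00225, adjusted p = 0.216 with an estimated correlation), as were 3 and 11 of 20 ATF4 and unfolded protein response genes (list alone, 3 and 12, adjusted p = 0.00945, adjusted p = 0.625 with an estimated correlation), including Asns (-1.51 ± 0.13) and Psat1 (-1.61 ± 0.13). For endoderm, 6 of 9 genes were higher and 3 lower (list alone, 6 and 3, adjusted p = 0.00388, adjusted p = 0.397 with an estimated correlation; 0.157 with limma on log2(FPKM + 0.1)), for fibroblasts 3 of 4 higher and 0 lower (edgeR; list alone, 3 and 0, adjusted p = 0.00888, adjusted p = 0.397 with an estimated correlation; 0.0521 with limma on log2(FPKM + 0.1)), and for KRAB zinc fingers 9 of 13 higher and 0 lower (edgeR; list alone, 9 and 0, adjusted p = 0.0259, adjusted p = 0.844 with an estimated correlation). For imprinted genes, 9 of 19 were higher and 5 lower (list alone, 9 and 5; camera adjusted p = 0.00347, adjusted p = 0.216 with an estimated correlation), with a median of 0.49 that turned to -0.17 with limma on log2(FPKM + 1), where the median over all genes was -0.58. Pou5f1 (-1.46 ± 0.19), Nanog (-1.12 ± 0.11), Esrrb (-1.01 ± 0.14) and Zfp42 (-0.56 ± 0.12) were lower in the nucleus, the last of these with 0.18 on quantile-scaled values. The camera test did not pass for naive pluripotency genes (8 higher and 16 lower of 33, list alone the same, adjusted p = 0.143) or for the lists left (up to 0.916).

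Comparing m6A peaks of the fractions asked where marks depended on Zc3h13. In the cytoplasm, scr lists held 15092 and 12405 peaks and knockdown lists 11311 and 12301. In the nucleus the numbers were 13369 and 12342 against 12189 and 11555. The difference of the means was 1942.5 peaks in the cytoplasm (599.0 without scr 1 and 3286 without scr 2) and 983.5 in the nucleus (470.0 without scr 1 and 1497 without scr 2), and it did not pass an exact two-sided permutation test (p = 0.33, the smallest that 6 splits allow). Covered length was 5.77 ± 1.14 Mb in scr and 3.93 ± 0.075 Mb in knockdown in the cytoplasm (SD, n = 2), and 5.12 ± 0.597 and 4 ± 0.474 Mb in the nucleus.

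Listed peaks also differed in position. Peaks near an annotated transcript end made up 28.0% ± 0.707 of cytoplasmic scr lists and 15.4% ± 0.707 of knockdown lists (SD, n = 2), and 26.2% ± 0.424 and 14% ± 0.424 in the nucleus. Peaks near a start made up 10.5% ± 0.99 and 20.7% ± 0.071 in the cytoplasm, and 9.9% ± 0.849 and 20.8% ± 0.707 in the nucleus. Peaks of several exonic blocks rose from 25.8% ± 0.707 to 47.5% ± 1.98 and from 21.8% ± 1.63 to 44.1% ± 1.06. In each of these comparisons both knockdown lists lay on the same side of both scr lists, and the exact permutation p was again 0.33, the smallest possible.

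**Figure D4:**
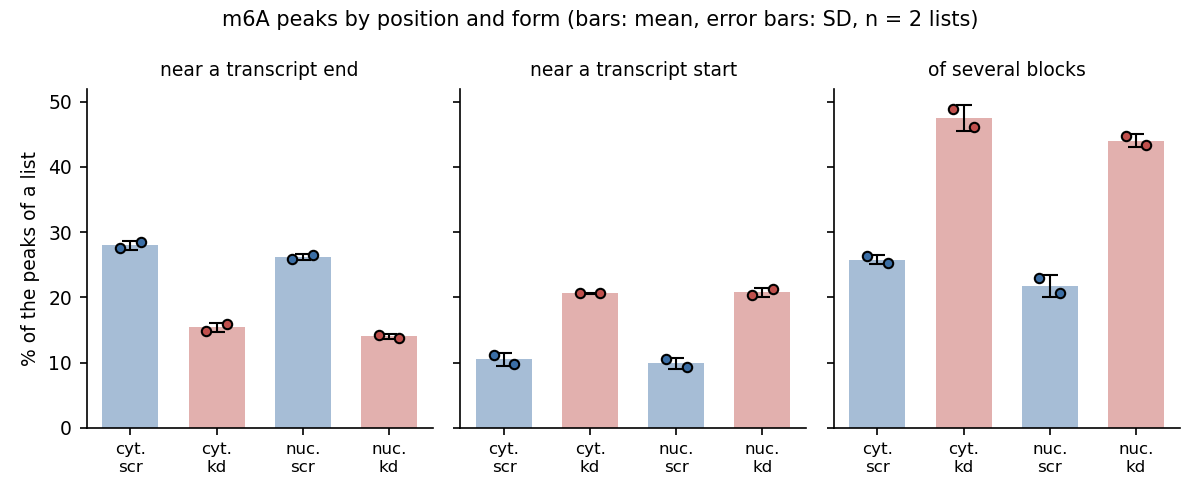
Percent of the peaks of a list (linear axis) that lie near a transcript end, near a transcript start or consist of several exonic blocks, with a point per list, bars for the mean and error bars for the SD (n = 2 lists). Near ends the knockdown lists average 15.4% (cytoplasm) and 14% (nucleus) against 28.0% and 26.2% in scr, and near starts 20.7% and 20.8% against 10.5% and 9.9%.

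Of 20106 cytoplasmic sites, 5439 had a peak in all 4 lists, 3920 (in 3353 genes) were lost in knockdown and 2419 (in 2082 genes) were gained. Dividing the same lists by replicate number gave 149 and 46 such sites, and the crossed division 102 and 10. Of 19146 nuclear sites, 5386 were in all 4 lists, 3952 were lost and 2770 gained, against 161 and 37, and 43 and 27, for the other divisions. In lists cut to equal length, 3338 cytoplasmic sites were lost and 2702 gained, and 3493 and 2960 in the nucleus. Among single-block peaks, a choice made after seeing the data, 3687 were lost and 932 gained in the cytoplasm, and 3852 and 989 in the nucleus. Lost sites lay near ends in 42.5% and 39.6% of cases and near starts in 3.9% and 3.3%. Gained sites lay near starts in 30.5% and 33.6% and near ends in 8.5% and 8.4%. Sites in all 4 lists lay near ends in 23.9% and 21.3%. Of the cytoplasmic lost sites, 2413 (61.6%) overlapped a nuclear lost site and 3 a nuclear gained site.

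Named genes showed both outcomes (coordinates on mm9). The Nanog peak at chromosome 6, 122663217 to 122663665, was lost in both fractions, and whole cells listed 1 Nanog peak in scr and 0 in knockdown. In nuclear knockdown 1 a peak near the Nanog start (122657645 to 122657794) was listed. Esrrb lost its peaks on chromosome 12 at 87811068 to 87829568 and near the transcript end at 87862219 to 87862458 in both fractions, and the peak at 87856437 to 87860333 in the nucleus, while this peak was in all 4 cytoplasmic lists. Klf4 (chromosome 4, 55540373 to 55543825), Zfp42 (chromosome 8, 44380752 to 44392363), Junb (chromosome 8, 87500870 to 87502617) and Myc (chromosome 15, 61821093 to 61821869) had a site with a peak in all 4 lists of the cytoplasm. Sox2 (chromosome 3, 34548927 to 34550788), Jun (chromosome 4, 94716440 to 94717166) and Tet1 (chromosome 10, 62295646 to 62301402) likewise kept a peak. In the nucleus, Myc lost a peak near its start (chromosome 15, 61817215 to 61817483). Zc3h13 lost its peak near the end (chromosome 14, 75739274 to 75743994) in both fractions and had another at 75721414 to 75723592 in all 4 cytoplasmic lists. Its cytoplasmic RNA fell from 54.2 and 41.5 CPM to 8.01 and 8.33. RNA of Nanog and Esrrb fell in both fractions too, as did that of Klf4 and Zfp42. For the lost peaks of Zc3h13, Nanog and Esrrb, loss of the mark and lower RNA cannot be told apart. Pou5f1 had a peak near its start (chromosome 17, 35642982 to 35643160) in scr 1 and both knockdown lists of the cytoplasm.

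The genes with the most lost sites were Kmt2a, a histone methyltransferase gene, and Sec16a of vesicle export (5 each) in the cytoplasm, followed by Gpc1, Socs2, Sugp2, Tbcel and Zfp704 (4 each). Gpc1, a cell surface proteoglycan gene, had 4 and 4 cytoplasmic peaks in scr and 0 and 0 in knockdown. Whole cells listed 1 Gpc1 peak in both conditions. Kmt2a still had peaks outside the cytoplasm, with 13 and 10 in nuclear scr lists, 13 and 14 in nuclear knockdown lists and 12 in whole cells of both conditions. Such counts do not show whether the same sites were kept. In the nucleus the protocadherin gene Pcdhgc4 lost 10 sites, and Dido1, Sec16a, Tacc2, Zbtb40 and Zfp276 lost 5 each, while whole cells listed 6 Dido1 peaks in both conditions. RNA changes of the genes in these rankings were not set against their lost sites. Loss of the mark and lower RNA therefore cannot be told apart for them.

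In whole cells, 5676 of 12368 scr peaks (45.9%, Wilson 45% to 46.8%) overlapped no knockdown peak, and 4733 of 11850 knockdown peaks (39.9%, 39.1% to 40.8%) overlapped no scr peak. With 1 list per condition these shares have no replicate check. Peaks without a partner lay near ends in 36.6% of cases in scr and 9.6% in knockdown, against 18.1% of scr peaks with a partner. These positions are midpoints of spans that include introns, unlike the exonic blocks of the fraction lists. The longest span was 264764 bp in scr and 2904728 bp in knockdown, so differing spans could move these shares. With overlapping peaks of a list counted once, Pcdhgc4 went from 19 to 2, Usf3 from 8 to 0, the cadherin gene Celsr3 from 7 to 0, the transcription factor gene Casz1 from 6 to 0 and Map10 from 4 to 0. Macf1, with 7 scr peaks that had no partner, went from 10 to 16. Esrrb went from 3 to 1 and Jun from 0 to 2, while Klf4, Sox2 and Zfp42 had as many in both (2, 2 and 1). Where numbers fell, loss of the mark and lower RNA were not told apart.

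Comparing RNA changes between genes that lost and kept whole-cell peaks asked whether loss of the mark goes with a change of level. The median log2(FPKM + 1) change was 0.077 in 2281 genes that lost their peaks, 0.12 in 4310 that kept one and 0.064 in 3764 without any. Permutations of these groups ran across genes, which are not replicates. Genes that lost peaks lay 0.040 below those that kept one (permutation p = 0.0171, adjusted p = 0.0256, and p = 0.0744 within 10 bins of expression). Lower RNA in knockdown might itself remove a listed peak, and bins of mean expression do not take this out. This difference therefore cannot show which of the changes came first. Genes that kept a peak lay 0.054 above those without (permutation p = 1e-05, the smallest possible, adjusted p = 2e-05). The difference of 0.014 between genes that lost peaks and those without did not pass (permutation p = 0.404, adjusted p = 0.485). None of these comparisons was binned by mRNA length. With edgeR fold changes the medians were -0.01, 0.02 and -0.02. The sign thus turned with the scaling both in genes that lost peaks and in genes without any. The median over all genes was 0.089 with limma on log2(FPKM + 1) and 0.001 in edgeR. With edgeR, the difference of genes that lost peaks from genes that kept one was -0.03 (permutation p = 0.0133). Of 25 naive pluripotency genes with a scr peak, Nanog, Prdm14, Gdf3 and Tcl1 lost theirs and 21 kept one.

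Comparing the nuclear share of marked and unmarked RNAs used 5644 genes with an m6A site in all 4 scr fraction lists and 3348 with none. In scr the median nucleus over cytoplasm ratio was -0.53 with and -0.63 without a site, both near the median of -0.58 over all genes, a difference of 0.10 where permuted groups centred on -0.08 (permutation p = 1e-05, the smallest possible, adjusted p = 2e-05). In knockdown this ratio shifted by 0.31 with and 0.43 without a site, around the shift of 0.35 over all genes, a difference of -0.11 (permuted 0.02; permutation p = 1e-05, adjusted p = 2e-05). With edgeR ratios from the fit with the block, which are relative to the TMM reference, the ratio in scr was 0.08 with and -0.09 without a site (difference 0.17) and its shift -0.06 and 0.09 (difference -0.15, permutation p = 1e-05 for both). On both scales the shift was the knockdown ratio minus the scr ratio. The same scr inputs thus entered the ratio and its shift with opposite signs, so these differences are not independent. Permutations ran across genes, which are not replicates, and were not binned by mRNA length.

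The list of Zc3h13-bound RNAs, which the authors deposited without values, held 3241 of the 11605 expressed genes. Tests of this list ran across genes, which are not replicates. It included 37 of 46 ribosomal protein genes and 10 of 33 naive pluripotency genes (Pou5f1, Nanog, Klf2, Tfcp2l1, Dppa2, Dppa3, Dppa5a, Gdf3, Tcl1 and Tdh). The share of naive pluripotency genes was near that over all expressed genes. Bound genes had a median mRNA of 1842 nt and a mean FPKM of 22.0 at the median, against 3194 nt and 7.34 for other genes. A whole-cell scr peak was listed for 51.0% of bound and 59.1% of other genes (odds ratio 0.721, 95% interval 0.665 to 0.782, Fisher p = 3.88e-15). At a mean FPKM of at least 5 these shares were 52.7% and 76.3% (odds ratio 0.347, Fisher p = 1.37e-103). Over all 11605 expressed genes, a site in all 4 scr fraction lists was found in 39.2% of bound and 54.3% of other genes (odds ratio 0.543, Fisher p = 2.47e-48). Within bins of expression, 1652 bound genes had a peak where permutation gave 2096 (permutation p = 1e-05, the smallest possible), and 1863 with bins of mRNA length added. Lost peaks were found in 693 bound genes (21.4% against 19%, odds ratio 1.16, Fisher p = 0.00385; permuted 612, p = 1e-05). Among genes with a scr peak, 41.9% of bound and 32.2% of other genes lost theirs (odds ratio 1.53, Fisher p = 6.99e-13), a test chosen after seeing the data. These 693 bound genes compare with 483 in permutations within expression bins and 547 with mRNA length added (permutation p = 1e-05 for both). A gene was classed as lost only if none of its scr peaks had a partner, which is easier with few peaks. The number of peaks per gene was not matched, so the excess cannot be tied to binding.

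RNA levels of bound genes changed no more often than those of others. Of bound genes, 1519 passed the edgeR threshold in knockdown (odds ratio 1.00, Fisher p = 0.983), where permutation within expression bins gave 1587 (p = 0.00239; p = 0.184 with mRNA length added). Rises were found in 703 (odds ratio 0.855, Fisher p = 0.00156; permutation p = 0.0632) and falls in 816 (odds ratio 1.17, Fisher p = 0.00143; permutation p = 0.103). At a mean FPKM of at least 5 these ratios were 0.906 (p = 0.076) and 0.999 (p = 1), and for falls the permutation p was then 0.0132. The median change was 0.077 in bound and 0.093 in other genes (permutation p = 0.644 within expression bins, adjusted p = 0.644).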

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

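Of the tests in this part, the comparison of sites held once by each of 4 lists was chosen after the peak positions were seen, and the other predictions were written before their result.

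The number of genes whose knockdown effect differed between nucleus and cytoplasm was picked out because a test of the difference itself passed, with 2524 genes in the fit with the replicate number as a block. Without the block 0 genes passed in edgeR (1494 at an unadjusted p under 0.05), 35 in limma on log2(FPKM + 1) and 108 in DESeq2. Neat1 (1.54 ± 0.26) and Diaph1 (-1.38 ± 0.16) are examples. No group of 4 RNA-seq knockdown libraries had a library far from the others in 112 measures, where chance gives about 1 in 20.

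Knockdown lists held fewer peaks near transcript ends and more near starts in both fractions, and a calling or annotation setting that differed between conditions could give this, since the longest peak spans 2904728 bp in all 5 knockdown lists and 156873 to 264764 bp in the 5 scr lists, and 78.3% of gained but 12% of lost cytoplasmic sites have several blocks. At 4044 cytoplasmic and 4049 nuclear sites held once by each list that share differed by at most -1.0 percentage points, but such sites cannot show a setting that decides which sites are listed. Weak peaks that come and go with depth could do so too, but among peaks below each list's median p the share near ends still differed by 14.2 points in the nucleus. Lower RNA of the marked genes might remove peaks, but at most 28.8% of lost sites lay in genes whose input RNA fell, and lost sites elsewhere lay near ends in 43.8% (cytoplasm) and 40.2% (nucleus), against 25.4% and 21.1% of sites in all 4 lists. Depletion of Zc3h13 and such a setting cannot be told apart here, because both go with the groups.

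Same-numbered fraction libraries deviated together from their group means across genes (genes are not replicates). A trend with mRNA length that differed between numbers 1 and 2 could give this, but after removing that trend the lowest of 6 correlations was still 0.565. A purity of the fractions that differed between numbers might also give it, but after removing the trend with the nucleus over cytoplasm ratio the lowest was 0.561. Both values argue against these as the whole cause. Depth also went with the number, at 26.8 to 37.5 M total fragments in number 1 and 18.6 to 20.7 M in number 2 inputs, and was not tested. The design holds no group that would give a biological explanation, so none was tested.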

How the results depend on the processing

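DESeq2, relative log expression factors, fits without Rn45s and Lars2, estimated correlations with the block, single-block peaks, edgeR values in the comparisons of gene groups, bins of mRNA length and bound genes among those with a scr peak are tests chosen after the data were seen. Groups of 2 libraries limit these results, as do fraction inputs with as few as 9.5 M fragments in genes, and the cause of the changes listed here was not tested. In fits without 1 library, a lone library is assumed to vary like the other groups. No paired analysis by replicate number was possible in RNA-seq because the labels of its groups share only replicate number 2. The RNA-seq library numbers used here follow the order of deposit. The set term compared RNA-seq libraries within a deposit set instead.

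In RNA-seq, 3048 genes passed without the set term, 1855 in set A and 2257 in set B, and 2801 to 4883 with 1 library left out, of which 3048, 1798, 2106 and 2572 to 4697 were among the 5437 calls in the same direction. In the order cytoplasm, nucleus and difference between fractions, limma on log2(FPKM + 1) called 516, 715 and 35 genes, on log2(FPKM + 0.1) 513, 729 and 45, and edgeR without a filter 4170, 4262 and 289. At a mean FPKM of at least 5, 1644 passed in the cytoplasm, 1549 in the nucleus and 3802 for nucleus over cytoplasm, where fewer genes were tested. Quantile scaling gave 1685 in the cytoplasm and DESeq2 108 for the difference. With 1 library left out the counts were 933 to 2450 in the cytoplasm and 832 to 2747 in the nucleus. With the replicate block, edgeR gave 5897, 5672 and 2524, DESeq2 5082, 4926 and 1904, and edgeR without Rn45s and Lars2 5889, 5743 and 2648. The block changed the call of no other gene or list (camera) that the report gives, and where the report counts the members of a list only without the block, the sum of rises and falls moved by at most 1.5 times.

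With an estimated correlation 0 gene lists passed in RNA-seq, 0 in the cytoplasm, 0 in the nucleus, 0 for the difference and 0 for nucleus over cytoplasm, with the block or without. On quantile-scaled values Sox2 (0.28) and Zfp42 (0.18) turned higher in the nucleus than in the cytoplasm of scr cells, without passing. The 554 results of genes chosen by the rule kept direction and side of the threshold in 5576 alternative values, passed anew in 422, no longer passed in 317 and turned in 2. With 1 library left out these counts were 3965, 22, 225 and 0.

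The sets correlated at 0.825 at a mean FPKM of at least 5. The rescue share was 87.2% for genes changed 2-fold and 95.8% for genes chosen over both sets, a choice that used the set A knockdown libraries and so favours the scr side. Among peaks below each list's median p, 2362 cytoplasmic sites were lost and 1540 gained, and 2260 and 1749 in the nucleus. Among single-block peaks 3687 and 3852 were lost and 932 and 989 gained. Whole-cell scr peaks without a partner made up 47.1% at an overlap of 50%, 47.9% at a listed p of 0 and 44.9% in lists of equal length, and knockdown peaks 41.6% at 50% and 41.1% in lists of equal length. The peak number difference stayed above 0, from 599.0 to 3286 in the cytoplasm and from 470.0 to 1497 in the nucleus without 1 list. The lost minus kept difference of -0.0403 did not pass within 10 bins (permutation p = 0.0744). For bound genes at a mean FPKM of at least 5, the odds ratios were 0.906 for rises and 0.999 for falls, below 1, and observed over permuted falls 0.943. Observed over permuted changes were 0.982 with mRNA length added.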

Other observations

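The search of gene families was chosen after the RNA-seq result was seen, as was the test that compares hairpins. The prediction for the test of knockdown strength was written before its result.

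Families of genes that share a symbol stem were tested beyond the fixed lists, and 6 of 165 stems passed camera in RNA-seq (0 with an estimated correlation, adjusted p = 0.924 for each). Of 9 Platr genes, long noncoding RNAs linked to pluripotency, 0 rose and 7 fell in edgeR, among them Platr4 and Platr22 (camera adjusted p = 0.00143). Of 9 Col genes 4 rose and 0 fell, namely Col4a2, Col4a1, Col2a1 and Col5a1 (0.00143). Of 52 Rpl genes 1 rose and 30 fell (0.00727), and of 53 Eif genes, which include those of translation initiation factors, 5 rose and 24 fell (0.0467). Of 21 Klhl genes, whose products include adaptors of ubiquitin ligases, 12 rose and 2 fell (0.0232). Of 141 Fam genes, which share a naming scheme and no function, 53 rose and 17 fell (0.0232). All 12 Pcdhga genes fell, but the stem did not pass (0.0588) and these genes share exons. Mmp2 and Mmp14 were among 6 of 8 Mmp genes that rose (0.138).

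For RNA-seq, the labels name the hairpins of set B (hairpin 1 in knockdown 3, hairpin 2 in knockdown 4) and not those of set A. They name no hairpin for the knockdown fraction inputs and m6A lists. The difference between knockdown 1 and 2 ran with that between knockdown 3 and 4 across 11605 genes (Pearson 0.799, Spearman 0.691, genes are not replicates). Whether set A may hold the same pair of hairpins in the same order stays an open hypothesis, because this correlation is the pattern itself and only the labels could settle it. A stronger knockdown in 1 library of each set could also give it, but removing the trend with the knockdown effect left a correlation of 0.781, which argues against that. The labels do not state the hairpins of set A, no comparison here uses this reading, and no biological explanation was tested.

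Zscan4c, a gene of the 2-cell-like state, stood at 8.75 and 11.7 CPM in scr 1 and 2, at 62.1, 7.15, 39.4 and 5.86 in knockdown 1 to 4, and at 10.9 in the rescue. On log2(CPM + 1) with TMM scaling, its difference was 2.94 between knockdown 1 and 2 and 2.54 between knockdown 3 and 4. Zscan4d and Zscan4f went the same way. Lef1 (-1.86 in both sets), Bcl11a, Nefl and Sall3 went the other way, as did Ccno and Efnb2. Differences of at least 2-fold the same way in both sets were found for 40 genes.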
